A study of Homo sapiens with 3 samples.

How the data were processed

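Gene expression was measured with Affymetrix oligonucleotide arrays in HEK293T cells, an established human embryonic kidney line that carries the SV40 large T antigen. Per the labels' protocols, growing cells were transduced with a lentivirus holding an empty pCDF1 vector, wild-type TRAF7 or the TRAF7 G536S mutant. Stable cells were selected in puromycin, RNA was extracted with TRIzol, and biotin-labelled cRNA was prepared from total RNA. TRAF7 is an E3 ubiquitin ligase with a RING finger and WD40 repeats, and the G536S change lies in the WD40 part. The labels give 1 array for each of the 3 groups. No group has replicates, so no p-value, standard error or count of significant genes is given, and a difference between 2 arrays holds the difference between the cultures, the extractions and the arrays as well as that of the constructs. The number of arrays limits the precision of every value.

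The deposited values are log2 intensities per probe set made by the authors with RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes), per the submitters' processing notes. The software version and the array's genome build are not given in the sources used here. The log base is not stated either and was inferred from the values: the highest value, 12.57, would exceed the top of a 16-bit scanner (11.09 as a natural log) if it were a natural log, so base 2 was used. The table holds 53617 probe sets per array. Medians were 1.04 in the empty vector array, 1.02 in the wild-type array and 1.01 in the G536S array, and 75th percentiles were 1.73, 1.85 and 1.86. The empty vector array was thus lower in the upper part of its values, a difference that remained after the authors' normalization. The correlation across all probe sets was 0.984 between wild type and empty vector, 0.982 between G536S and empty vector, and 0.989 between G536S and wild type.

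Probe sets were named from the platform annotation, with symbols updated through the Entrez ID in a RefSeq gene table of the GRCh38.p14 assembly. The annotation lists 25713 of the probe sets, of which 23871 name 1 gene and 1842 name several. The other 27904 are unnamed here. Of the probe sets with 1 gene, 22569 matched through the Entrez ID, 90 of them with a newer symbol, and 1302 kept the older symbol. A gene with several probe sets was given the value of the probe set with the highest mean over the 3 arrays, which left 22395 genes. Genes with a mean at or above the median of these means (1.21 on the log2 scale) were kept for counts and named genes: 11198 genes, 10077 of them protein-coding. Most genes sit near background on these arrays, where differences are compressed. Near-identical copies, such as the FAM72 and ZNF families, 5S RNA copies, immunoglobulin segments and pseudogenes, can share probe sequence, so their values are uncertain.

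For each comparison the log2 difference was taken as first group minus second, and genes at least 2-fold or 1.5-fold apart were counted. The median difference of each of 29 gene lists was set against 10000 random lists of the same size drawn from 20 bins of mean level. A list is called outside the random lists when its percentile is below 2.5 or above 97.5, which chance gives for 1.45 of 29 lists. The values of 1 list and of some members of another are not reported here. Members of a list move together, so this describes the arrays and is an optimistic yardstick. The genes named are the 12 highest and 12 lowest of each comparison among genes with usual symbols, TRAF7, up to 4 members of each list outside the random lists in the direction of its median, and members of 5 signalling lists at least 2-fold apart. These rules, the lists and the alternatives were fixed before the data were examined. Members of a list given for context, and genes singled out in the closing section, were chosen after their values were seen. Both construct comparisons share the empty vector array, so their correlation and overlap were set beside 1000 simulated sets of 3 unchanged arrays. These sets had the same normal noise in each array, set by level from the spread of G536S versus wild type.

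The alternatives were the mean of a gene's probe sets, no expression filter, a filter at the 75th percentile (2.87), quantile normalization of the deposited columns, centring each array on its median, cyclic loess (a level-dependent centring), a floor at the 25th percentile (0.86), and, for lists, members passing the filter alone. Counts of protein-coding genes alone were added after seeing the data. Quantile normalization and cyclic loess used limma 3.58.1 in R 4.3.3, and the rest used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

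The counting was tested on simulated data for the wild type versus empty vector comparison over 22395 genes. Of genes changed 2-fold, 50% were counted as 2-fold apart in the right direction, and 8% of those changed 1.5-fold, 82% of those changed 3-fold and 86% of those changed 4-fold. Of 11022 unchanged genes, 2 were counted. The simulated noise was normal and was set from the spread of G536S versus wild type, the smallest of the 3 comparisons. The count of unchanged genes is thus too low a guide to false calls in the data. For the G536S versus empty vector comparison, over 22395 genes, 5.5% of 200 unchanged lists lay outside the random lists. Of 100 lists of genes that all passed the filter, each member raised by 0.3 on the log2 scale, 100% were found. The gene lists used here also hold members below the filter, so this is too favourable a guide for lists with many such members.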

Results

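The data are 3 arrays of HEK293T cells that stably carried an empty vector, wild-type TRAF7 or TRAF7 G536S, with 1 array per group and no replicates. Differences are log2 values of one array minus another, and no statistical test between groups was possible. TRAF7 was read first, as a check of the labels. Its single probe set (16815001) read 5.66 with the empty vector, 8.11 with wild-type TRAF7 and 7.35 with G536S, which is a difference of 2.46 (5.49-fold) for wild type and 1.70 (3.24-fold) for G536S. The G536S array was lower than the wild-type array, with a difference of -0.76. Which part of the TRAF7 transcript the probe set reads, and so whether it reads the construct, the cell's own gene or both, was not determined.

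**Figure D1:**
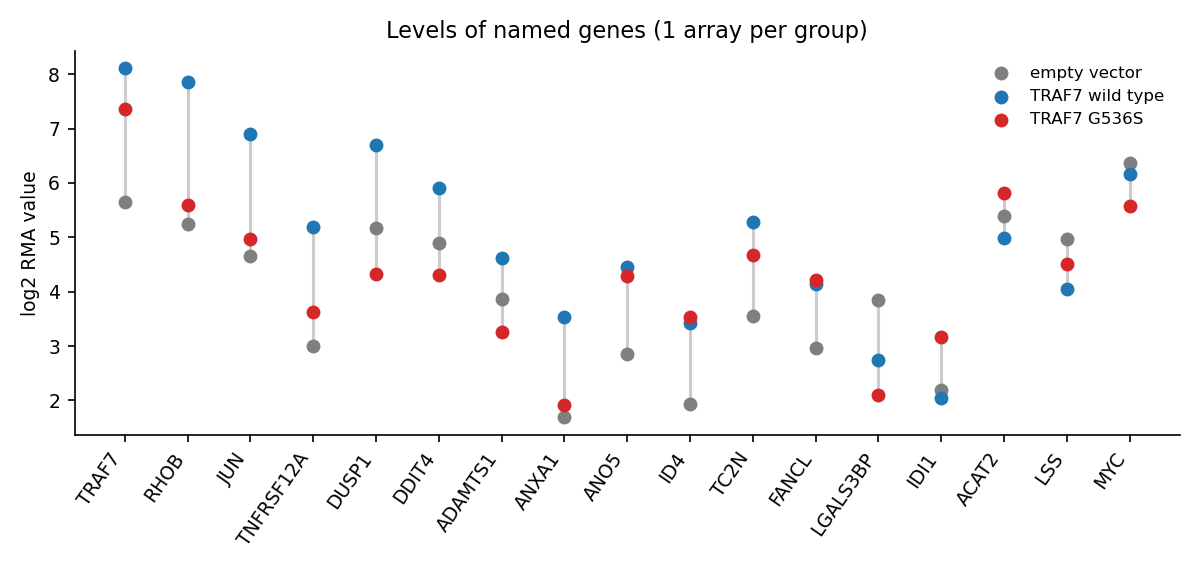
Log2 RMA values (vertical axis) of named genes in the empty vector, wild-type and G536S arrays, 1 point per array. TRAF7 was 5.66, 8.11 and 7.35 in these arrays, and RHOB was 5.24, 7.85 and 5.60.

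Wild-type TRAF7 was compared with the empty vector to ask what differs when the protein is added. The largest difference was RHOB, a small GTPase, at 7.85 against 5.24 (2.61, 6.12-fold). JUN, an AP-1 subunit, was higher by 2.25, TNFRSF12A, the receptor for the cytokine TWEAK, by 2.18, and DUSP1, a phosphatase that acts on MAP kinases, by 1.52. ANXA1, a membrane-binding annexin, was higher by 1.85, and the zinc finger gene ZNF492 by 1.87. TC2N was higher by 1.73, ANO5, a member of the anoctamin family, by 1.60, ID4, an inhibitor of basic helix-loop-helix factors, by 1.49, VAMP4, a SNARE protein, by 1.43, and SOX7, a transcription factor, by 1.40.

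Among the genes named as lowest, LGALS3BP, a secreted galectin-binding glycoprotein, was 2.75 with wild type and 3.85 with the empty vector (-1.10). CORO1A, an actin-binding protein, differed by -1.21, the homeobox gene HOXA2 by -1.17, GPC3, a cell-surface proteoglycan, by -1.08, AP5B1 by -1.06 and NAT8L by -1.03. The pseudogene or uncharacterised loci TSSC2 and TPTEP1 differed by -1.23 and -1.15, EOLA2 by -1.09, RN5S188 by -1.16, and the immunoglobulin segments IGKV1-37 and IGHD2-21 by -1.48 and -1.15.

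In all, 89 genes were at least 2-fold higher and 18 at least 2-fold lower with wild type, and 607 and 201 were at least 1.5-fold apart. Protein-coding genes made up 71 of the higher and 8 of the lower genes. The higher share was 83.2% of the genes 2-fold apart, 58.2% after quantile normalization and 63.0% after cyclic loess. The median gene passing the filter differed by 0.08, and quantile normalization moved that median by -0.11.

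Of the 29 lists, 4 lay outside the random lists. The YAP/TAZ targets had a median of 0.14 (percentile 99.1 among random lists), with 15 of 23 measured members above 0; CCN1, a matricellular protein, was higher by 0.60, FJX1 by 0.59, PTPN14 by 0.55 and GADD45A by 0.41. NOTCH targets had a median of -0.23 (percentile 0.10), with 3 of 11 measured members above 0. HEY2, a NOTCH-induced repressor, differed by -0.95, NRARP by -0.68, the receptor NOTCH1 by -0.53 and HES4 by -0.36. HEY2 lies among neighbouring genes whose mean was higher with wild type, while HEY2 itself was lower.

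Cholesterol synthesis genes had a median of -0.18 (percentile 0.05), with 4 of 18 measured members above 0. LSS, which forms lanosterol, differed by -0.92, MVD, of the mevalonate pathway, by -0.84, ACAT2 by -0.41 and NSDHL by -0.36. Epithelial adhesion genes had a median of -0.08 (percentile 2.34), with 9 of 24 measured members above 0 and none 1.5-fold apart; PKP2 differed by -0.31, SPINT2 by -0.29, DSP by -0.17 and CLDN4 by -0.16. The calls for YAP/TAZ targets and epithelial adhesion genes were lost when only members passing the filter were used, and that for epithelial adhesion genes also after quantile normalization and cyclic loess.

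The AP-1 and immediate early genes as a list stayed within the random lists. Their median was -0.06 and their mean 0.21, so the 2 differ in sign. JUN and DUSP1 were 2-fold higher, FOSL1, an AP-1 subunit, was higher by 0.91 and ATF3, a stress-induced factor, by 0.75, while MYC differed by -0.21 and JUNB by -0.12. In the MEKK3-ERK5 list, the 3 members at least 1.5-fold higher were KLF6 (0.83), ADAMTS1, a secreted protease (0.76), and MAP2K5, the kinase that acts on ERK5 (0.63). The list median was 0.08 (percentile 63.9), within the random lists, with 11 of 19 measured members above 0. ATF4 and amino acid response genes had a median of 0.18 (percentile 97.2), within the random lists, and lay above them after quantile normalization and cyclic loess.

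G536S was compared with the empty vector to ask the same of the mutant. Of the genes named by the rule, which leaves out snoRNA, miRNA and similar symbols, the pseudogene PDCL3P4 had the highest difference (2.02), followed by TRAF7. ID4 was higher by 1.60, RTKN2 by 1.47, ANO5 by 1.43, MSTO1 by 1.43, ZNF724 by 1.30, MTERF2, a mitochondrial transcription factor family member, by 1.26, FIGNL1, a recombination factor, by 1.24, and FANCL, the ubiquitin ligase of the Fanconi anaemia core complex, by 1.24. SNHG8, a host gene of small nucleolar RNA, was higher by 1.25. UIMC1, which binds ubiquitin at DNA breaks, was higher by 1.48 on one probe set and by 0.36 on its second, so its size is uncertain. Over 212 genes with a second probe set past the filter level, differences on the first and second correlated at r of 0.508 for wild type versus empty vector, 0.498 for G536S versus empty vector and 0.289 for G536S versus wild type. Of the 3 of these genes 2-fold apart between G536S and empty vector on the first probe set, 3 had the same direction on the second and 0 were 1.5-fold apart there; the 1 gene 2-fold apart between G536S and wild type did not keep its direction. RHOB, JUN and TNFRSF12A were higher by 0.36, 0.32 and 0.62, and DUSP1 differed by -0.84.

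Of the genes named as lowest, LGALS3BP came first, at 2.09 against 3.85 (-1.75). The other low genes were TPTEP1 (-1.61), EOLA2 (-1.60), IGHD2-21 (-1.53), GIPC3 (-1.44), IGKV1-37 (-1.38), RN5S188 (-1.24), the neuronal splicing factor RBFOX3 (-1.22), QPCTL (-1.20), the Golgi protein YIF1B (-1.19), NBPF3 (-1.19) and TIGD5 (-1.18).

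In all, 104 genes were at least 2-fold higher and 30 at least 2-fold lower with G536S, and 680 and 233 were at least 1.5-fold apart. Protein-coding genes made up 52 and 17 of the 2-fold genes, and genes for small nucleolar RNA (snoRNA), which guide the modification of other RNAs, made up 35 of those higher. The higher share was 77.6%, 48.6% after quantile normalization and 54.1% after cyclic loess. The median gene passing the filter differed by 0.10, and quantile normalization moved that median by -0.13.

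**Figure D2:**
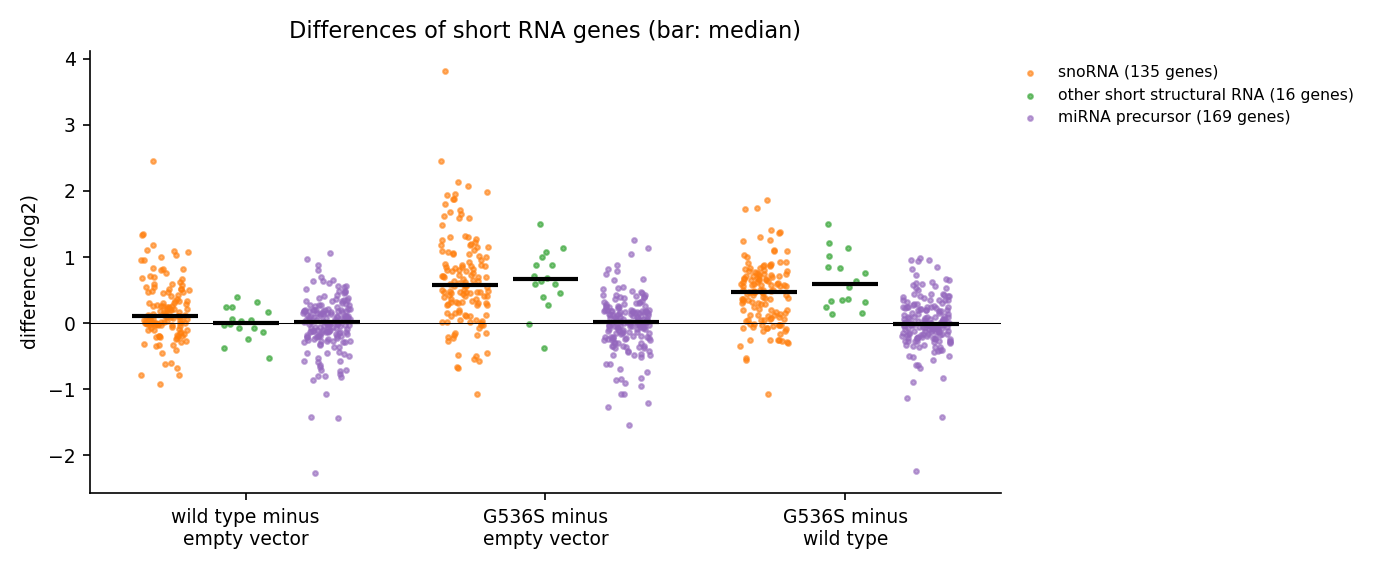
Log2 difference (vertical axis) of each snoRNA gene (orange), other short structural RNA gene (green) and miRNA precursor (purple) in the 3 comparisons, with black bars at medians. The snoRNA medians were 0.11, 0.57 and 0.48.

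Lists outside the random lists numbered 6. G2/M and mitosis genes had a median of 0.34, above all random lists, and 27 of 31 measured members were above 0. MAD2L1, a spindle checkpoint protein, was higher by 0.94, the phosphatase CDC25C by 0.65, the kinetochore motor CENPE by 0.62 and the kinase TTK by 0.52; with wild type the list had a median of 0.16 (percentile 90.9), within the random lists. Cholesterol synthesis genes had a median of 0.31 (percentile 99.2), with 14 of 18 above 0. IDI1 was higher by 0.97, SC5D by 0.88, INSIG1, a sterol-regulated brake on the pathway, by 0.65 and MSMO1 by 0.46, whereas LSS and MVD differed by -0.46 and -0.33. Ribosomal proteins had a median of 0.24 (percentile 98.8), with 31 of 36 above 0; RPL29 was higher by 0.74, RPL37 by 0.61, RPS23 by 0.60 and RPL32 by 0.59.

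The other lists outside were lower. AP-1 and immediate early genes had a median of -0.18, below all random lists, with 5 of 20 members above 0. DUSP1 and MYC differed by -0.84 and -0.79, NR4A2, an orphan nuclear receptor, by -0.61 and JUNB by -0.47. Hypoxia and glycolysis genes had a median of -0.05 (percentile 1.72) with 11 of 28 above 0, against a median of 0.08 for random lists. In this list the glycolytic enzymes PFKP and HK2 differed by -0.47 and -0.39, P4HA2 by -0.23 and the glucose transporter SLC2A1 by -0.20. The only member of this list 1.5-fold apart, EGLN1, went the other way (0.64). NOTCH targets had a median of -0.11 (percentile 2.35), with HEYL at -0.60, NRARP at -0.42, HEY2 at -0.38 and HES4 at -0.16, a call lost when only members passing the filter were used.

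**Figure D3:**
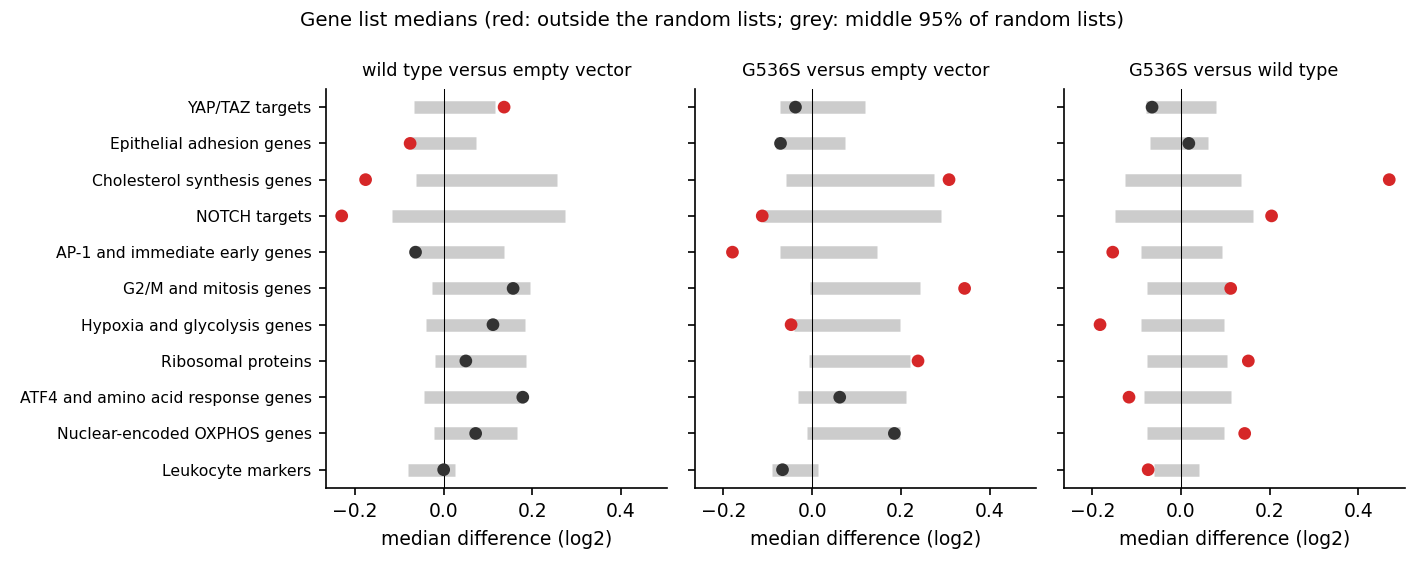
Median log2 difference (horizontal axis) of the 11 lists outside the random lists in at least 1 comparison, with the range of random lists in grey and medians outside it in red. Cholesterol synthesis genes lay at -0.18, 0.31 and 0.47 in the 3 comparisons.

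The differences of the 2 constructs from the empty vector were then set against each other. Across genes passing the filter, which are not independent replicates, Pearson's r was 0.634 and Spearman's rho 0.624. Simulated unchanged arrays of equal noise that share 1 control gave 0.500 and 0.481. The covariance was 0.0652 against a simulated 0.0262, a difference of 0.0390. TRAF7, ANO5, ID4, TC2N and FANCL were among 22 genes 2-fold higher with both, and LGALS3BP, TPTEP1, EOLA2 and RBFOX3 among 10 genes 2-fold lower with both, where simulated unchanged arrays that share one control gave 0.003 and 0.005 on average and independent lists would share 0.827 and 0.0482. The counts of 22 and 10 became 11 and 14 after quantile normalization, 12 and 12 after cyclic loess, and 13 and 1 with the filter at the 75th percentile. No gene was 2-fold apart in opposite directions. The simulation held no extra noise in the empty vector array and no extreme differences, so its low overlap cannot show an excess over noise. The robust spread (an SD from the median absolute deviation) was 0.266 for wild type and 0.276 for G536S against the empty vector. Between the constructs it was 0.226. The single empty vector array cannot be split, so part or all of this agreement may come from that array alone. Of the 71 protein-coding genes 2-fold higher with wild type, 14 were also 2-fold higher with G536S, 30 were 1.5-fold to 2-fold higher, and 27, RHOB and JUN among them, were below 1.5-fold.

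**Figure D4:**
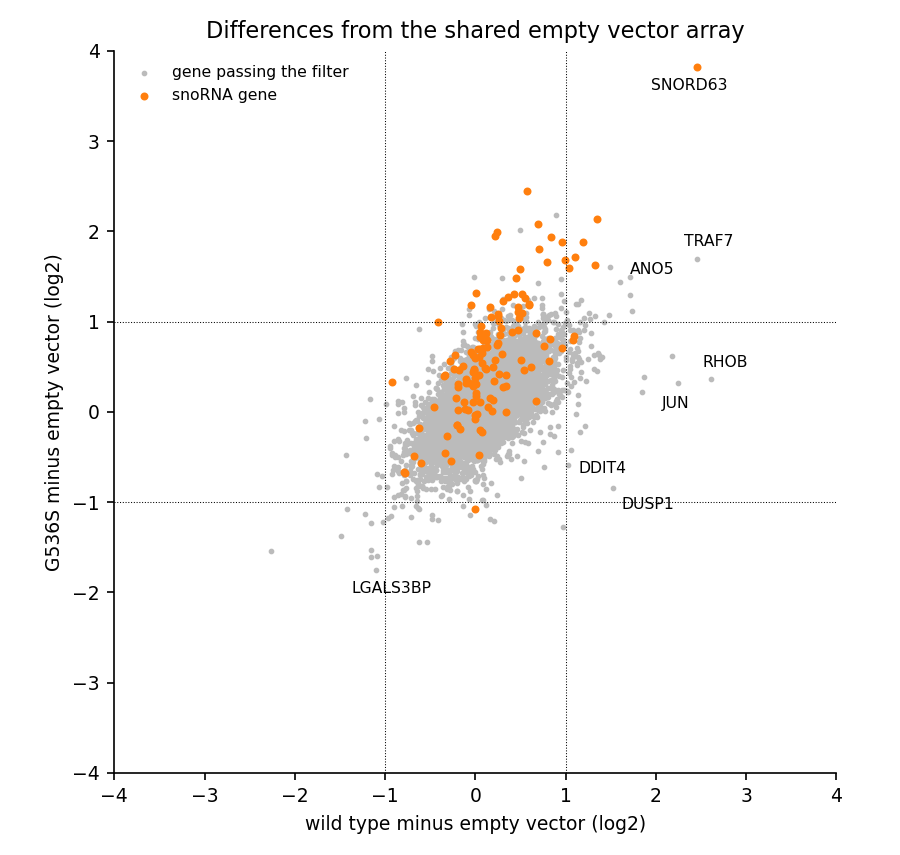
Log2 difference from the empty vector array for wild-type TRAF7 (horizontal) and G536S (vertical), 1 point per gene passing the filter, with snoRNA genes in orange and dotted lines at a 2-fold difference. Both axes share the same control array, which gave a correlation of 0.500 in simulated unchanged arrays of equal noise. The observed r was 0.634.

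The G536S array was compared directly with the wild-type array, a comparison that does not use the empty vector array. Of the genes named by the rule, DUSP1 (-2.37), RHOB (-2.25) and JUN (-1.93) had the lowest differences, followed by ANXA1 (-1.63), DDIT4, a stress-induced inhibitor of mTORC1 (-1.61), TNFRSF12A (-1.56), the matrix protein TNC (-1.49), ZNF492 (-1.48), RASGRF2, an exchange factor for RAS (-1.39), UBE2Q2P16 (-1.37), ADAMTS1 (-1.36) and CHAC1, which degrades glutathione (-1.36). The genes named as higher with G536S were RN5S132 (1.54), PDCL3P4 (1.52), HOXA2 (1.30), MTARC1 (1.24), PLEKHJ1 (1.13), TSSC2 (1.13), IDI1, an isomerase of isoprenoid synthesis (1.12), ADCY1 (1.10), the interferon-induced IFITM3 (1.07), KRCC1 (1.04) and SNAR-H (1.02). UIMC1 was higher by 1.18 on one probe set and differed by -0.12 on its second. In all, 30 genes were at least 2-fold higher and 30 at least 2-fold lower, of which 9 and 24 were protein-coding. At the 1.5-fold level 243 genes were higher and 203 lower.

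Lists outside the random lists numbered 9. Cholesterol synthesis genes had the highest median, 0.47, above all random lists, with 17 of 18 members above 0; ACAT2 was higher by 0.81, SC5D by 0.72 and NSDHL by 0.72. Ribosomal proteins had a median of 0.15 (percentile 99.9), with RPL29 higher by 0.89, RPL12 by 0.70, RPS23 by 0.55 and RPS19 by 0.51. Nuclear-encoded OXPHOS genes had a median of 0.14 (percentile 99.9), a list that with G536S against the empty vector was within the random lists (percentile 95.7) and above them after cyclic loess; COX8A was higher by 0.62, NDUFB10 and COX5B by 0.46 each and NDUFB3 by 0.41. NOTCH targets had a median of 0.20 (percentile 99.2), with 7 of 11 measured members above 0. HEY2 was higher by 0.57, NOTCH1 by 0.42, NRARP by 0.26 and NOTCH3 by 0.21, while HEYL differed by -0.35. G2/M and mitosis genes had a median of 0.11 (percentile 97.7), with KIF2C higher by 0.44, CENPF by 0.40, CENPE by 0.34 and MKI67 by 0.33.

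Hypoxia and glycolysis genes had a median of -0.18 (percentile 0.01), with NDRG1 at -0.76, VEGFA, an angiogenic factor, at -0.55, HK2 at -0.42 and PDK1 at -0.35. AP-1 and immediate early genes had a median of -0.15 (percentile 0.04), with FOSL1 at -0.67 and MYC at -0.58 after DUSP1 and JUN. ATF4 and amino acid response genes had a median of -0.12 (percentile 0.42), with the cystine transporter SLC7A11 at -0.62 and STC2 at -0.48 after DDIT4 and CHAC1. Leukocyte markers had a median of -0.07 (percentile 0.75), but only 3 of 21 measured members passed the filter. CD79B, LCP1, CD4 and CD79A differed by -0.26, -0.21, -0.15 and -0.15 near background. The only member 1.5-fold apart, CORO1A, passed the filter and went the other way (0.93). The calls for G2/M genes, NOTCH targets and leukocyte markers were lost when only members passing the filter were used, and that for G2/M genes also with the mean of a gene's probe sets. All 31 measured G2/M members passed the filter, so the first loss for that list did not come from dropped members.

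The other 18 lists lay within the random lists in all 3 comparisons, with percentiles from 2.83 to 91.3, though the heat shock, kidney, neuronal, TGF-beta and WNT lists lay outside in some comparison under another setting. The 18 lists include the MEKK3-ERK5, NF-kB, RAS-ERK, TGF-beta, mesenchymal, interferon, p53, apoptosis, TRAF family, G1/S, unfolded protein response, heat shock, WNT, neuronal, kidney, endothelial and housekeeping lists. TRAF7 has been studied in NF-kB and MEKK3 signalling. Of the NF-kB targets 26 were measured and 9 passed the filter. None of them was 1.5-fold apart in any of the 3 comparisons, and NFKBIA was higher by 0.29 with wild type and by 0.41 with G536S.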

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

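Of the tests below, the comparison with the TRAF7 level and the rescaling test for RHOB, JUN, TNFRSF12A and DUSP1 were chosen after the result was seen. With 1 array per group, none of the differences between the constructs given here was tested.

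DUSP1, a phosphatase that acts on MAP kinases, was higher than the empty vector with wild-type TRAF7 (1.52) and lower with G536S (-0.84). DDIT4, an inhibitor of mTORC1, went the same ways (1.03 and -0.59), as did the protease gene ADAMTS1 (0.76 and -0.61). RN5S132, a 5S RNA copy named only in the older annotation, went the opposite ways (-0.62 and 0.92). Cholesterol synthesis genes lay below the random lists with wild type (median -0.18) and above them with G536S (0.31). The direct comparison of G536S with wild type gave 0.47, which comes from the same arrays and is not separate support.

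RHOB, JUN, TNFRSF12A and DUSP1 were higher in the wild-type array than in both others. Scaling was argued against: over 3 rescalings the smallest of the 4 wild-type minus empty vector differences, the side that rescaling moves more, was 1.41, and the smallest of the 4 wild-type minus G536S differences was 1.55. A response in proportion to the TRAF7 level stays open, because the mean G536S difference of the 4 genes was 0.0535 of their mean wild-type difference, against a TRAF7 ratio of 0.691, but the genes were picked for being lower with G536S, which fixes a low value. A serum or handling response at harvest stays open, because 1 of FOS, FOSB, EGR1, IER2 and ATF3 was at least 1.5-fold higher with wild type, where the test needed 2 for that cause and none against it; ATF3 was that gene (0.75 with wild type and 0.78 with G536S), while FOS, FOSB, EGR1 and IER2 differed by -0.05, -0.08, -0.16 and -0.23 with wild type at levels of 2.49 or less. A difference between the constructs in how they act on these genes also stays open as an untested hypothesis, since 1 culture of each cannot separate it from a difference between cultures.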

How the results depend on the processing

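The count of protein-coding genes alone was chosen after seeing the data; the other settings were planned. Of 102 counts and correlations under all settings, 79 stayed within 1.5 times the main count or the correlation's interval and 23 moved; of 522 list medians 500 stayed and 22 moved; of 705 values of named genes 703 stayed and 2 moved. No named gene and no list outside the random lists changed sign, but the balance of higher and lower genes for G536S versus empty vector turned after quantile normalization. Removing the filter gave the same counts of 2-fold genes, which says nothing about stability, since genes below it lie near background, where signal limits what can be seen. No paired analysis was possible because each group has 1 array, and no replicate could be left out.

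Where counts moved, the filter at the 75th percentile tests fewer genes. It left 51 higher and 4 lower for wild type versus empty vector, 57 and 15 for G536S versus empty vector, 19 and 16 for G536S versus wild type, and 13 and 1 shared by both constructs. Quantile normalization gave 53 and 38, then 53 and 56, with 11 genes higher in both, and cyclic loess gave 58 and 34, then 60 and 51, with 12 higher in both. Protein-coding genes alone gave 8 lower for wild type, 52 and 17 for G536S versus empty vector, and 9 higher for G536S versus wild type. The correlation was 0.648 with no filter; its cause was not tested. Of the 107 and 134 genes 2-fold apart from the empty vector, 76 and 90 were shared with cyclic loess, and 59 of the 60 between G536S and wild type.

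Some lists within the random lists lay outside under another setting. For wild type versus empty vector these were ATF4 genes (above, with the mean of probe sets, quantile normalization, cyclic loess or members passing the filter alone), neuronal markers (below, cyclic loess) and kidney markers (below, members passing the filter alone). For G536S versus empty vector they were OXPHOS genes (above, both normalizations and members passing the filter alone), neuronal markers (below, both normalizations), and TGF-beta targets and leukocyte markers (below, members passing the filter alone). For G536S versus wild type they were heat shock genes (below, mean of probe sets or floor), kidney markers (above, floor) and WNT targets (below, members passing the filter alone).

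More genes were 2-fold higher than lower with either construct than with the empty vector, and the lower upper values of the empty vector array are a candidate cause. After cyclic loess the higher share was 63.0% with wild type and 54.1% with G536S, and after quantile normalization 58.2% and 48.6%. The test set in advance, on cyclic loess, needed 40% to 60% in both for level-dependent scaling, or over 70% in both against it. The wild-type value lies between these bounds and the quantile values within the first, so scaling stays open as the whole cause.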

Other observations

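None of the genes singled out here were fixed before the data were examined, and the 16 short RNA genes matched to a current RNA gene were chosen as a set after their values were seen; the tests of snoRNA carry-over, containing genes, rescaling and gene order were set before their results, and the paired comparison of snoRNA genes with their containing genes was added after them.

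Among genes outside the naming rule, the miR-221 precursor MIR221 read 4.64 with the empty vector, 5.61 with wild type and 3.36 with G536S, the same order as DUSP1. BHLHE40, a clock and hypoxia repressor, was 3.79, 3.91 and 2.76 in these arrays. SLC4A11, a membrane transporter, was 4.34, 4.27 and 3.20. GALNT6, which starts mucin-type O-glycosylation, was 1.59, 2.70 and 1.56. KIF5C, a kinesin, was 2.04 with the empty vector, 3.31 with wild type and 3.07 with G536S, and RAB23 was 2.89, 4.02 and 4.09.

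Genes for snoRNA were higher in the G536S array. Over 135 snoRNA genes the median difference was 0.57 from the empty vector and 0.48 from wild type, while wild type differed from the empty vector by 0.11 (0.01 after level-centring). SNORD63 read 3.62 with the empty vector, 6.07 with wild type and 7.44 with G536S, SNORA23 read 7.71, 7.95 and 9.70, and SCARNA4 read 4.34, 4.56 and 6.29. Of the 135 genes, 54 were at least 1.5-fold higher than in the wild-type array and 1 lower. Precursors of miRNA (169 genes) had medians of 0.01, 0.01 and -0.02 in the 3 comparisons.

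Scaling was argued against, since the snoRNA median, 0.48, was 0.45 or higher under each of 3 rescalings. Carry-over of short RNAs in general, which could follow from RNA extraction or labelling, stays open: 81 other short structural RNA genes had a level-centred median of 0.16 (bootstrap interval 0.11 to 0.31), between the bounds set in advance (0.12 and 0.23). These genes divide, as 16 matched to a current RNA gene had a median of 0.57, with RNU5F-1 higher by 1.51 and RNU4ATAC by 1.14, and 65 named only in the older annotation or as pseudogenes, mostly near background, had 0.11. Of the 81 genes, 22 passed the filter at the 75th percentile and had a level-centred median of 0.53 (bootstrap interval 0.23 to 0.77). At that filter 76 snoRNA genes had 0.56. Higher levels of the genes that contain the snoRNA genes were argued against as the whole cause, since snoRNA genes exceeded their containing genes by a median of 0.37 over 91 pairs (bootstrap interval 0.26 to 0.42), though 74 containing genes had a median of 0.0736 with an upper end of 0.123, which passed the bound of 0.121 set in advance, so a part in it stays open. An effect of the G536S construct was not tested, as 1 array carries the pattern.

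Differences from the empty vector were also not spread evenly along the genome. A candidate explanation is a copy number difference between the cell pools over blocks of neighbouring genes. With each gene's difference centred on genes of like level and limited to 1 on the log2 scale, the largest mean over 100 neighbouring protein-coding genes was 0.236 for wild type minus empty vector, in the block from FBXL4 to PEX7, where the 99th percentile of the largest mean over 1000 shuffles of the gene order was 0.134. The same block had the largest mean for G536S minus empty vector (0.187 against 0.132), and 75 and 76 of its 100 genes were above 0 after this centring. Between G536S and wild type the largest mean in any block was 0.0962, below its shuffled value of 0.110. The test set in advance also needed a least size, which lies between 0.187 and 0.236. Wild type minus empty vector met both parts, while G536S minus empty vector passed its shuffled value but not the least size. Neighbouring genes also share base composition and length, which was not tested. Both comparisons use the same empty vector array, so the block may belong to that array or its cells.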
